A study of Mus musculus with 24 samples.

How the data were processed

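H3K27ac ChIP-seq of liver was analysed in 12 libraries, 1 per mouse, in 4 groups of 3: control fasted, knockout fasted, control refed and knockout refed. Per the labels' protocols, male C57BL/6J mice with a floxed Gata4 gene received AAV8-Tbg-Cre (knockout) or an empty AAV8 vector (control) at 8 weeks of age and were killed 7 days later, at 9 weeks. Fasted mice had a 12 h fast, and refed mice a 12 h fast followed by 12 h on a diet with 69% sucrose and 10% fat. The labels give each mouse a number that is the same within a group and differs between groups, so a shared cage or litter cannot be told apart from group. The 12 input libraries of the series were not analysed here.

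The signal values are those the authors deposited in a table of 63686 regions. Each value is a whole number of reads in the region divided by 1 factor per library, and every library has the same total over the regions. Whole reads were recovered from the step of each column (all values within 0.01 of a whole read), which gave 22.2 to 30.4 M reads in regions per library and a value per read of 0.836 to 1.15. Per the submitters' processing notes the tools were FastQC, Trim Galore, Bowtie2, SAMtools, MACS2, bedtools, DiffBind, edgeR, HOMER and deepTools on the build mm9. Versions, the treatment of reads that map to several places and whether input reads were subtracted are not given in the sources used here. Per the file headers the regions were annotated with HOMER on mm9, and the gene and annotation class of each region are taken from there.

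Other columns and tables of the authors were used only beside the main tests. A deposited column gives the interval of a GATA4 ChIP peak at most 500 bp from a region; the antibody is named in the labels' protocols, and the libraries behind the peaks are not part of this series. A further deposited column gives the authors' adjusted p of fasted against refed control liver where it was under 0.05. The authors' 4 comparison tables give log2 ratios and a false discovery rate, a p-value adjusted by the authors, per the file headers, for regions under 0.05. The sign of each log2 ratio was checked against the group means, and that of the genotype table was turned.

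Main tests used limma 3.58.1 in R 4.3.3 on log2 of the value plus a pseudocount of 1, with empirical Bayes moderation and an intensity trend. All 12 libraries entered 1 fit with 4 groups and a shared spread, and no covariate was used because the labels give no batch. The contrasts were knockout against control in fasted and in refed liver, refed against fasted liver in each genotype, their interaction and the knockout effect averaged over feeding states. Regions with a Benjamini-Hochberg adjusted p under 0.05 over all regions were called. These choices, the gene lists, the rule for named genes and all alternatives but those named below were fixed before the data were examined. Use of the GATA4 peak column was added afterwards.

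Named genes were Gata4, Gata6, Abca1, Srebf1, Fasn, Pck1 and Cyp7a1 in every contrast, and the 10 largest rises and 10 largest falls per contrast among called regions. The latter needed a mean at or above the median region and 3 libraries of a group all outside the range of the other 3, with 1 region per gene and predicted genes left out. Up to 4 members of each list with the smallest adjusted p completed the rule. Some genes that the rule picked are not described here, and counts and tests include them. The 21 lists cover LXR targets, lipoproteins, cholesterol synthesis, lipogenesis and glycolysis, gluconeogenesis and fasting, fatty acid oxidation and ketogenesis, bile acids and hepatocyte transcription factors. They also cover pericentral and periportal genes, the unfolded protein response, the clock, the acute phase, interferon response, fetal liver, proliferation, and markers of endothelial, stellate, Kupffer, lymphocyte and cholangiocyte cells. Each gene was represented by the region with the highest mean over all libraries. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over 84 tests. Lists share some genes, and lists of markers hold genes that more than 1 liver cell type expresses.

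A fold against a group at 0 in all 3 libraries is given against a floor, the group mean of 3 reads per library. Floors cover counting error only and are no bound if a step set low values to 0. SEs rest on the spread between mice, and odds ratio intervals treat regions as independent. Promoter and GATA4-bound shares were compared with two-sided Fisher exact tests, with odds ratios and 95% confidence intervals. Matched GATA4 shares used uncalled regions in 20 bins of mean value and 10 of width, with a common odds ratio over the bins. Overlap with the authors' tables counted any shared base.

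Alternatives were pseudocounts of 5 and 0.5, leaving out the regions with the lowest mean values, median-ratio rescaling, quantile normalization, cyclic loess, array quality weights, fitting only the groups of a contrast, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. For lists, the region nearest the TSS and the mean over all regions of a gene were tried, beside quantile normalization and leaving out each library. The other alternatives were not run for lists. Leaving out regions at 0 in any library, thinning reads to the smallest library, edgeR or DESeq2 with library totals only, and the bound share after rescaling were chosen after seeing the data. The median-ratio, quantile and loess settings assume that most regions, or the whole distribution, do not change between groups.

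Replicates differed by more than counting: between libraries of a group the chi-square per degree of freedom was 4.50 to 9.13 and Pearson r of log2 values across regions was 0.954 to 0.967. The fits were tested on simulated data with 200 changed regions in the 63686: 38% to 44% of 2-fold and 80% to 90% of 4-fold changes were recovered, 10% to 14% of 1.5-fold changes, and 1 to 6 of 72 to 76 calls were false. A list raised 1.3-fold was called by camera, and none of 80 tests of unchanged lists was. Simulated regions were drawn independently, so this does not test camera where the genes of a list vary together. In the real data the estimated correlation within a list reached 0.555 for cholesterol synthesis. A planned search for GATA motifs was not run, because no genome of the build mm9 was at hand. Tables were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures drawn with matplotlib 3.10.9.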

Results

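Acetylation of histone H3 lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by ChIP-seq in whole liver of 12 male mice. The mice carried a floxed Gata4 gene, which encodes a zinc-finger transcription factor of hepatocytes, and had received either an AAV8 vector with Cre recombinase under the hepatocyte Tbg promoter (knockout) or an empty AAV8 vector (control). Each genotype was taken either after a 12 h fast or after a 12 h fast followed by 12 h on a high-sucrose diet (refed), giving 4 groups of 3 mice. The table held 63686 regions with a median width of 1557 bp, of which 51.2% lay in introns, 34.4% between genes and 6.93% at promoters. Reads in regions per library were 25.9 ± 3.22 M in control fasted, 24.2 ± 1.10 M in knockout fasted, 28.8 ± 1.52 M in control refed and 22.9 ± 0.674 M in knockout refed liver (mean ± SD in mega-reads, n = 3 each). The range over all libraries was 22.2 to 30.4 M. Values below are normalized reads per region; changes are log2 ratios ± SE from limma with its Benjamini-Hochberg adjusted p over all regions, with n = 3 mice per group. The gene given for a region is the one with the nearest transcription start site (TSS), which does not show that the region regulates that gene. Each region has a single annotation class, so a wide region can span a TSS without being counted at a promoter. Coordinates are 1-based on mm9.

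Feeding state separated the libraries along the first principal component and genotype along the second. The first component held 47.3% of the variance, with fasted libraries between -122 and -88.3 and refed libraries between 70.7 and 143. The second held 11.3%, with control libraries between -88.5 and -17.6 and knockout libraries between 21.4 and 70.5.

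**Figure D1:**
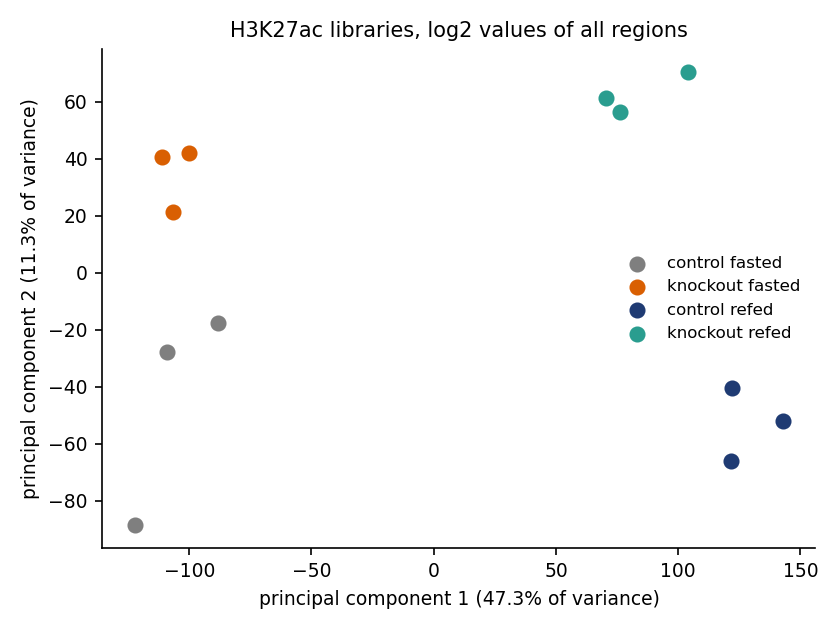
First and second principal components of the log2 H3K27ac values of all regions, in arbitrary units, 1 point per library, coloured by group (3 libraries each). Refed libraries lie between 70.7 and 143 on the first component, and knockout libraries between 21.4 and 70.5 on the second.

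The locus of the deleted gene comes first. At Gata4, 7 regions were annotated and none was called for knockout in either feeding state. The strongest (chromosome 14, 63845908 to 63872243) is annotated as intronic but is wide and spans the TSS. It held 3594 ± 168 in control and 4071 ± 167 in knockout fasted liver (0.18 ± 0.06, adjusted p = 0.227). It held 4981 ± 213 and 5490 ± 328 in refed liver (0.14 ± 0.06, 0.267). The labels do not say which exons are floxed, other cells of the liver keep the gene, and acetylation of the locus therefore does not test the deletion. With refeeding this region rose in control (0.47 ± 0.06) and knockout liver (0.43 ± 0.06), while a region upstream (chromosome 14, 63904553 to 63907343) fell in both (-1.86 ± 0.25, adjusted p = 4.83e-05, and -1.27 ± 0.25, adjusted p = 0.00167).

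Refed and fasted control mice were compared to see how acetylation of the liver differs after refeeding on a sucrose-rich diet. Refed mice had a 12 h fast plus 12 h of feeding, so the clock time of the fast or of killing differed between the feeding states. Effects of time of day therefore cannot be told apart from those of refeeding in either genotype. The strongest lipogenic response was at Scd1, which encodes stearoyl-CoA desaturase. A wide region that is annotated as between genes but spans the Scd1 TSS (chromosome 19, 44472414 to 44497988) went from 669 ± 150 to 6048 ± 161 (SD, n = 3). The log2 change was 3.20 ± 0.15 (adjusted p = 6e-09). Of 29 measured genes of lipogenesis and glycolysis, 18 rose and 4 fell (19 and 5 adjusted over the list alone). They included Pgd of the pentose phosphate pathway (1.41 ± 0.08), Pklr, the liver pyruvate kinase (1.24 ± 0.07), and Fasn, the fatty acid synthase (0.89 ± 0.05). Srebf1, which encodes the lipogenic regulator SREBP-1, rose by 1.06 ± 0.10, from 2488 ± 303 to 5151 ± 186. Of 23 cholesterol synthesis genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), among them squalene epoxidase Sqle (1.22 ± 0.15), Fdps (1.10 ± 0.13) and Tm7sf2 (1.03 ± 0.12). camera, which compares a list with all other genes, gave adjusted p = 0.000111 for lipogenesis and adjusted p = 0.281 with an estimated correlation. For cholesterol synthesis the values were 0.00331 and adjusted p = 0.71 with an estimated correlation. These counts and tests use 1 region per gene; over all regions of the same genes 62 rose and 44 fell of 142 for lipogenesis, and 31 rose and 19 fell of 102 for cholesterol synthesis. That call was lost when the mean over all regions of a gene was used (adjusted p = 0.0663, within a range of 1.93e-06 to 0.0663 over its alternatives).

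Genes of the fasted state moved the other way. Pck1, the cytosolic enzyme that commits carbon to gluconeogenesis, fell from 7349 ± 1100 to 1809 ± 460 in a region between genes (chromosome 2, 172959269 to 172975657; log2 change -2.04 ± 0.19, adjusted p = 2.3e-06). The glucocorticoid-responsive Fkbp5 changed by -1.84 ± 0.22. Of 21 genes of gluconeogenesis and fasting 10 fell and 2 rose (10 and 4 adjusted over the list alone); Nr3c1, the glucocorticoid receptor, was among those that rose (0.45 ± 0.07). Of 39 genes of fatty acid oxidation and ketogenesis 17 fell and 2 rose (20 and 3 adjusted over the list alone). The fatty acid omega-hydroxylases led them, with Cyp4a14 (-3.32 ± 0.28), Cyp4a10 (-2.97 ± 0.18), Cyp4a31 (-2.57 ± 0.15) and Cyp4a32 (-1.67 ± 0.11). Of 22 bile acid genes 7 fell and 3 rose (8 and 3 adjusted over the list alone), including Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-1.10 ± 0.18), and the exporter Abcc3 (-0.94 ± 0.08). Of 19 periportal hepatocyte genes 9 fell and 3 rose (11 and 3 adjusted over the list alone), with Pigr at -0.59 ± 0.06 and Ctsc at -1.16 ± 0.14. Of 23 acute phase genes 8 fell and 5 rose (11 and 5 adjusted over the list alone), with metallothionein Mt1 at -1.28 ± 0.15, serum amyloid Saa3 at -1.02 ± 0.13 and Orm1 at 0.81 ± 0.10. camera adjusted p was 0.00795 for gluconeogenesis, 4.12e-08 for fatty acid oxidation, 0.00243 for bile acids, 0.000497 for periportal genes and 0.0125 for the acute phase, all toward lower values. None held with an estimated correlation, for which the adjusted p was 0.579, 0.543, 0.579, 0.281 and 0.543. The acute phase call was also lost without control fasted replicate 1 (adjusted p = 0.0723) or control refed replicate 2 (0.0626), in a range of 0.00381 to 0.0723 over the libraries left out.

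Other groups, on 1 region per gene, had no camera call, and all but fetal liver genes held both rises and falls. Of 22 clock genes 6 rose and 8 fell (7 and 9 adjusted over the list alone), with Npas2 at 2.46 ± 0.20, Arntl at 0.89 ± 0.13 and Usp2 at -1.13 ± 0.17 (camera adjusted p = 0.225). Of 22 genes of the unfolded protein response 10 rose and 2 fell (11 and 2), with the chaperone Hyou1 at 0.44 ± 0.09 and Creld2 at -1.01 ± 0.14 (0.16). Of 25 interferon response genes 7 rose and 2 fell (7 and 2), with Bst2 at 0.86 ± 0.12 (0.974). LXR target genes numbered 5 higher and 3 lower of 16 (camera adjusted p = 0.37), lipoprotein genes 6 and 6 of 27 (0.494; median 0.04 but camera toward lower). Hepatocyte transcription factors numbered 5 and 5 of 21 (0.419; mean 0.03 but median -0.05 and camera toward lower) and pericentral genes 7 and 8 of 22 (0.0952). Proliferation genes numbered 4 higher and 1 lower of 18 (0.315), and fetal liver genes 0 higher and 3 lower of 8 (0.21). Adjusted over the list alone, the counts were 5 and 3 for LXR targets, 7 and 7 for lipoproteins, 5 and 5 for transcription factors, 8 and 10 for pericentral genes, 4 and 1 for proliferation and 0 and 3 for fetal genes. Over all regions of these genes falls outnumbered rises for hepatocyte transcription factors (13 higher and 65 lower of 211), pericentral genes (17 and 47 of 166), lipoproteins (25 and 36 of 164) and fetal genes (0 and 6 of 27). Rises outnumbered falls for LXR targets (20 and 16 of 85), the clock (30 and 26 of 113), the unfolded protein response (19 and 15 of 73), interferon (10 and 8 of 72) and proliferation (11 and 6 of 63).

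Among markers of other cell types that whole liver holds, only the cholangiocyte list had a camera call with refeeding in control liver. Of 10 cholangiocyte markers 6 rose and 1 fell (7 and 1 adjusted over the list alone), including Tspan8 (2.24 ± 0.17), Elf3 (1.35 ± 0.20) and Epcam (1.00 ± 0.20). camera gave adjusted p = 0.042 (adjusted p = 0.579 with an estimated correlation). That call was lost on the region nearest the TSS (0.159), without control fasted replicate 1 (0.0505) or without control refed replicate 1 (0.0884), in a range of 0.0332 to 0.159 over its alternatives. Sinusoidal endothelial markers had 4 higher and 4 lower of 25 (camera adjusted p = 0.776), with Egfl7 at 0.55 ± 0.05 and Stab2 at -1.37 ± 0.25, and 24 higher and 39 lower of 286 over all their regions. Stellate markers had 3 higher and 0 lower of 19 (1 and 0 adjusted over the list alone; 0.925), Kupffer and macrophage markers 2 and 0 of 14 (0.925) and lymphocyte markers 1 and 0 of 14 (0.843). For endothelial, Kupffer and lymphocyte markers the counts adjusted over the list alone were the same. camera pointed down where median and mean were positive for endothelial and Kupffer markers, and where the median was positive and the mean negative for lymphocyte markers and fetal liver genes.

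Over all regions, 8378 rose and 10705 fell in refed control liver, 30.0% of those tested, and 3142 and 5909 of them changed by more than 2-fold. Of the changes that the fixed rule named, several ran from or to 0. Regions near Pdcl3 and Reck went from 0 in all 3 fasted controls to refed means of 288 ± 25.6 and 248 ± 11.4. Unless low values were set to 0, these rises are at least 96.5-fold and 83.2-fold over the floor. The same held near Lrp2bp (at least 60.6-fold), and regions near Taar8c, Pnpla5, Plch2, Cck, Rapgef6 and Rgs7 rose from fasted means of 1.53 to 8.03, near the floor, to refed means of 226 to 574. Regions near Fendrr and Adam24 were at 0 in all 3 refed controls and were at least 92.5-fold and 73.7-fold lower. Regions near Mad1l1, Pknox2, Mup20, Tfap2d, Gpc6 and Cux2 fell to refed means of 1.55 to 7.24 from fasted means of 142 to 457, and a region near Megf9 fell from 680 ± 172 to 58.8 ± 102. The rule asks that the 3 libraries of a group lie outside the range of the other 3, which chance alone gives for 10% of regions. Promoters made up 10.9% of the regions that rose, 1.73% of those that fell and 7.44% of those not called. The odds ratio was 1.52 (95% confidence interval 1.40 to 1.64; two-sided Fisher exact adjusted p = 3.8e-24) for rising and 0.219 (0.187 to 0.254) for falling regions. Neighbouring regions are not independent, and promoter shares here and below were not matched on value and width.

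Refeeding of knockout mice asked whether the response holds without hepatocyte Gata4. In the same Scd1 region the values were 964 ± 227 and 5195 ± 87.1 (log2 change 2.45 ± 0.15). Fasn (0.90 ± 0.05), Pgd (1.52 ± 0.08), Pklr (1.03 ± 0.07) and Srebf1 (0.87 ± 0.10) rose as well. The camera calls of lipogenesis, cholesterol synthesis, gluconeogenesis, fatty acid oxidation, bile acids, the acute phase and periportal genes that follow were each lost with an estimated correlation (adjusted p of 0.344, 0.71, 0.579, 0.344, 0.543, 0.298 and 0.281 in this order). Of the 29 lipogenic genes 17 rose and 4 fell (17 and 7 adjusted over the list alone; camera adjusted p = 0.007). Of the 23 cholesterol synthesis genes 13 rose and 1 fell (16 and 1; 0.00331), with Sqle at 1.29 ± 0.15. Pck1 changed by -1.49 ± 0.19 and Fkbp5 by -1.16 ± 0.22 among 8 fallen and 2 risen gluconeogenic genes (8 and 2; 0.00331). Fatty acid oxidation genes had 21 lower and 0 higher of 39 (22 and 0; 9.42e-14), with the enoyl-CoA isomerase Eci2 at -2.03 ± 0.20, Cyp4a10 at -1.66 ± 0.18 and the PPARα-responsive Vnn1 at -1.62 ± 0.16. Bile acid genes had 11 lower and 1 higher (13 and 1; 2.99e-05). Acute phase genes had 10 lower and 1 higher (12 and 3; 0.000111), with Saa3 at -1.43 ± 0.13, and periportal genes 9 lower and 3 higher (10 and 3; 0.00101). The counts in parentheses are those adjusted over the list alone, followed by the camera adjusted p. Over all regions of the same genes 53 rose and 36 fell for lipogenesis and 27 rose and 14 fell for cholesterol synthesis.

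In knockout liver camera also called lipoprotein genes lower after refeeding (8 lower and 4 higher, 9 and 4 adjusted over the list alone; 0.00812). With counts in the same order, it also called lower hepatocyte transcription factors (4 and 1, 6 and 3; 0.0347) with Nr1i3 at -0.95 ± 0.14, and pericentral genes (10 and 5, 11 and 8; 0.0458) with Cyp2e1 at -0.90 ± 0.10. No camera call in knockout refeeding held with an estimated correlation, for which the lowest adjusted p was 0.281. Quantile normalization ended the calls of lipoproteins (0.0788), gluconeogenesis (0.0663), transcription factors (0.584) and pericentral genes (0.0788), and the mean over all regions of a gene ended those of cholesterol synthesis (0.286) and pericentral genes (0.184). Over their alternatives the adjusted p ranged from 0.00554 to 0.0788 for lipoproteins, 0.00168 to 0.0663 for gluconeogenesis, 0.0223 to 0.584 for transcription factors, 0.0103 to 0.184 for pericentral genes and 0.000565 to 0.286 for cholesterol synthesis. The transcription factor call was lost without knockout fasted replicate 3 (0.0938) or knockout refed replicate 1 (0.0624). The pericentral call was lost without control fasted replicate 2 (0.057), knockout fasted replicate 1 (0.0673), control refed replicates 1 (0.064) or 3 (0.0513), or knockout refed replicates 1 (0.0522) or 2 (0.0637).

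The lists with no call in knockout refeeding had camera adjusted p of 0.925 (LXR targets, 5 higher and 2 lower), 0.136 (unfolded protein response, 11 and 2) and 0.637 (clock, 5 and 3). They were 0.102 (interferon, 10 and 2), 0.225 (fetal liver, 2 and 3) and 0.385 (proliferation, 5 and 0). Among cell type markers, cholangiocyte genes had 6 higher and 0 lower (7 and 0 adjusted over the list alone; 0.0712), with Tspan8 at 1.56 ± 0.17 and Epcam at 1.56 ± 0.20. Kupffer and macrophage markers had 3 higher and 0 lower (4 and 0; 0.309), with Cx3cr1 at 1.28 ± 0.20 and Clec7a at 1.20 ± 0.21. Endothelial markers had 3 and 3 (0.394), stellate markers 3 and 1 (0.843) and lymphocyte markers 1 and 1 (0.582). Adjusted over the list alone, the counts were 5 and 2 for LXR targets, 12 and 2 for the unfolded protein response, 5 and 3 for the clock, 12 and 2 for interferon, 2 and 3 for fetal genes and 5 and 0 for proliferation. Those of endothelial, stellate and lymphocyte markers were the same on either adjustment. The camera direction was opposite to the median and mean for clock, endothelial and stellate genes, and to the median but not the mean for lymphocyte genes.

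**Figure D2:**
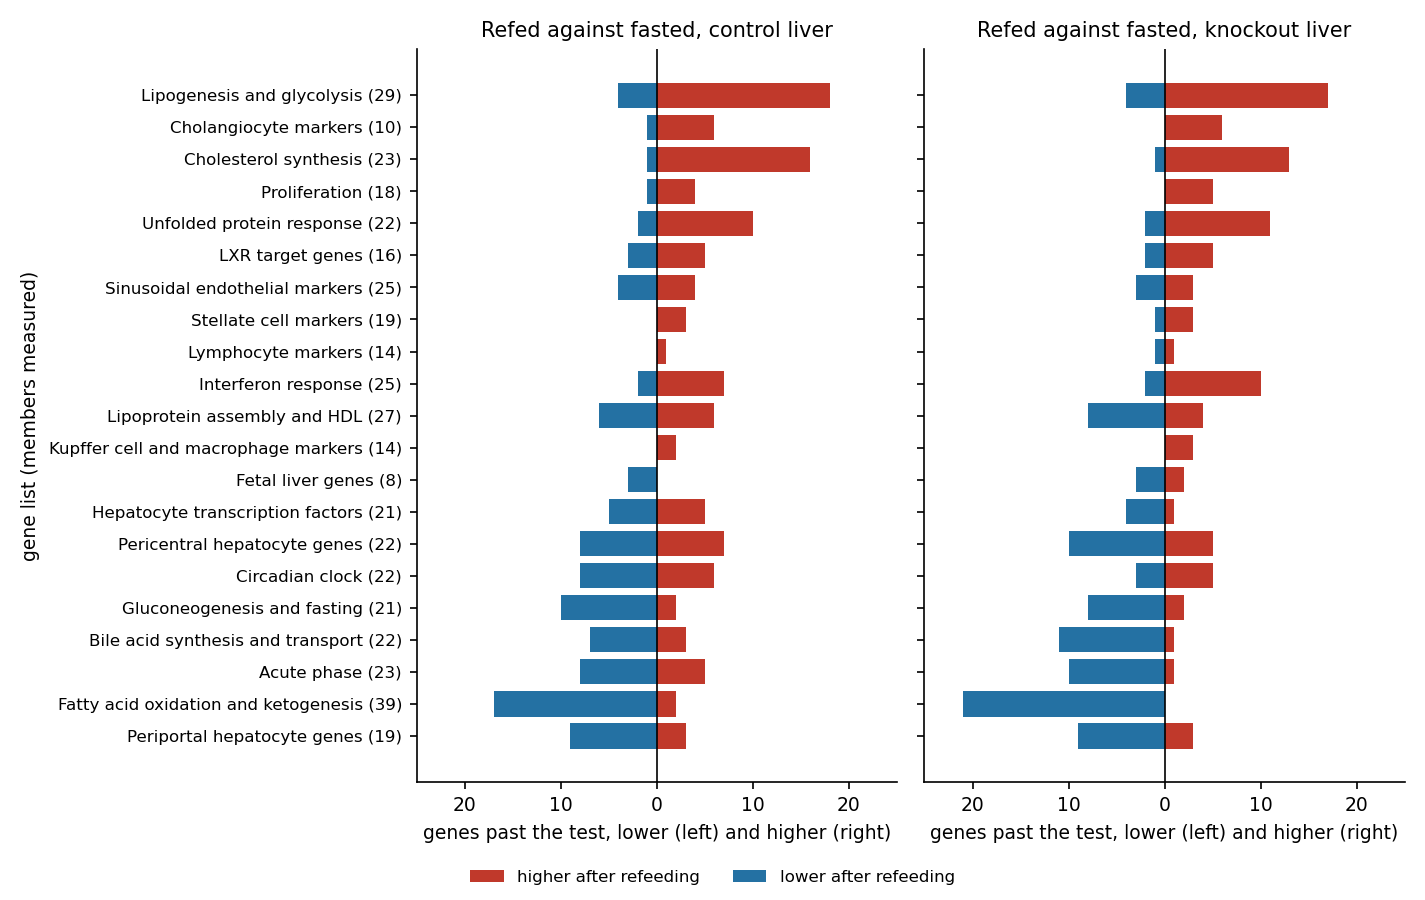
Number of measured genes per fixed list called higher (right of 0) or lower (left of 0) after refeeding at a limma adjusted p under 0.05, in control and knockout liver, on 1 region per gene. Fatty acid oxidation had 17 lower genes of 39 in control and 21 in knockout liver, and lipogenesis 18 and 17 higher genes of 29.

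In knockout liver 8466 regions rose and 7252 fell after refeeding, 24.7% of those tested. Promoters made up 12.3% of the risen and 2.00% of the fallen regions against 6.72% of those not called (odds ratios 1.95 and 0.283). The largest rises that the rule named were near Clcn7 (0.734 ± 1.27 to 598 ± 64.4, the former under the floor), Reck (at least 92.4-fold), Cck (at least 78.9-fold), Pdcl3 (at least 69.8-fold), Ppp2r5c (at least 72.0-fold), Pnpla5, Mall, Plch2, Cacng4 and Abcc6. The largest falls were near Adam24 (at least 59.9-fold), Megf9, Pknox2, Sox6, Gpc6, Fendrr, Sall3, Bfar and Tfap2d. The call near Megf9 was lost without knockout refed replicate 2 (adjusted p = 0.054). Across all regions the refeeding changes of the genotypes correlated with Pearson r = 0.77 and Spearman rho = 0.71, where regions are not independent replicates. Called in both were 5456 rises and 5477 falls, against 1114 and 1219 for independent lists, and 37 regions were called in opposite directions. Over regions called in control liver the slope of the knockout on the control change was 0.66. Over regions called in knockout liver the slope of the control on the knockout change was 0.92. These slopes run in opposite directions and over differently selected regions, so they are not estimates of the same quantity.

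**Figure D3:**
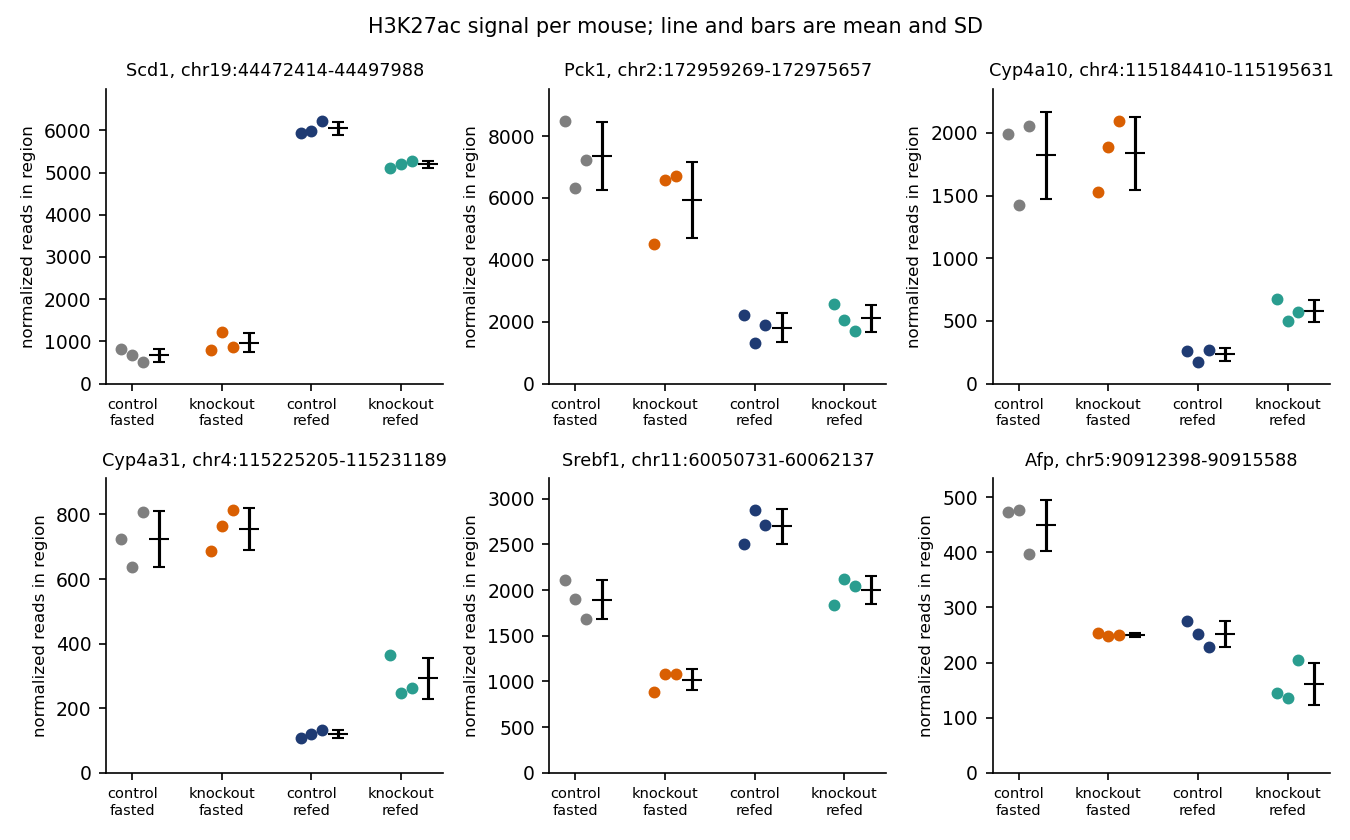
Normalized H3K27ac reads per library (points) with the group mean and SD (bars, n = 3) in 6 regions: those nearest Scd1, Pck1, Cyp4a10, Cyp4a31, Afp and the GATA4-bound region upstream of Srebf1. The Cyp4a10 region lies at 234 ± 50.5 in control refed and 581 ± 88.0 in knockout refed liver, and the Afp region is lower in knockout than in control liver in either feeding state.

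In fasted liver, knockout against control addressed what Gata4 does before a meal. The region nearest Afp, the fetal serum protein alpha-fetoprotein (chromosome 5, 90912398 to 90915588, between genes, with a GATA4 peak), held 449 ± 45.9 in control and 250 ± 3.44 in knockout liver (log2 change -0.83 ± 0.15, adjusted p = 0.026). A GATA4-bound region upstream of Srebf1 (chromosome 11, 60050731 to 60062137, in an intron of another transcript) fell from 1896 to 1020 (-0.89, adjusted p = 0.00121); it was singled out after its values were seen. Regions near Muc13, a membrane mucin (-1.87 ± 0.30), Olfml2b (-2.34 ± 0.42) and Acsl4, an acyl-CoA synthetase (-1.70 ± 0.31), fell, as did those near Ivns1abp, Cript, Dntt, Vmn2r19, Atxn7l3b, F2rl2 and Rap2a (-2.10 to -1.72). Regions that rose lay near Tcf24 (216 ± 49.1 to 708 ± 68.5; 1.73 ± 0.17), Sox11, a developmental transcription factor (2.21 ± 0.40), and the clock repressor Nr1d2 (1.62 ± 0.29). A region near Lrp2bp was at 0 in all 3 controls and at 21.6 ± 5.89 in knockouts, at least 7.24-fold higher. The others named were near Cars, Fam69c, Nrn1, Tas2r134, Sh3bgrl2 and Macrod1 (1.75 to 3.63).

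In total 199 regions rose and 156 fell in fasted knockout liver, 0.557% of those tested, while 8466 had an unadjusted p under 0.05. The count moved with single libraries: 179 without control fasted replicate 1, 918 without replicate 2, 163 without replicate 3, 105 without knockout fasted replicate 1, 187 without replicate 3 and 233 without control refed replicate 3. With only the fasted groups in the fit 21 rose and 38 fell, DESeq2 gave 610 and 568 (911 and 520 on library totals), and the share of higher regions was 47.0% with median-ratio rescaling against 56.1%. Of the 20 genes named by size, Lrp2bp and Tcf24 kept their call under every alternative run for them. Fitting only the fasted groups ended 16 of the 20 calls, and leaving out control fasted replicate 1 or knockout fasted replicate 1 ended 11 each. Leaving out control fasted replicate 3 ended 9, knockout fasted replicates 3 and 2 ended 7 and 5, and each other library 3 or fewer. The Afp call was lost without control fasted replicate 1 (0.0814) or knockout fasted replicates 1 (0.0965), 2 (0.054) or 3 (0.0739), with 0.0965 the highest over all alternatives.

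Among gene groups in fasted knockout liver, fatty acid oxidation genes were shifted upward: 1 of 39, Acaa1b, a peroxisomal thiolase, rose (0.46 ± 0.09, adjusted p = 0.037). Adjusted over the list alone 3 rose and 0 fell, and the median log2 change was 0.12. camera gave adjusted p = 0.000111 at the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.579). At the preset correlation it held with quantile normalization, with either other choice of region and without any single library. Acute phase genes were shifted up (0 higher and 0 lower of 23, 1 and 0 adjusted over the list alone; camera adjusted p = 0.0125, adjusted p = 0.543 with an estimated correlation). Socs3 was at 0.33 ± 0.07 (adjusted p = 0.06). The call was lost without control fasted replicate 2 (0.281) or knockout fasted replicate 3 (0.0779), in a range of 0.000235 to 0.281. Gluconeogenic genes were shifted down (0 and 0 of 21, 0 higher and 4 lower adjusted over the list alone; 0.0331, adjusted p = 0.662 with an estimated correlation), with Lpin1 at -0.44 ± 0.11 (adjusted p = 0.092). Quantile normalization ended that call (0.19), as did leaving out control fasted replicate 1 (0.562) or knockout fasted replicates 1 (0.106) or 2 (0.057), and the mean over all regions reversed its direction (0.93). Over all regions of these genes 1 rose and 1 fell of 226. Its adjusted p ranged from 0.00079 to 0.93.

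Among markers of other cell types, camera called the Kupffer and stellate lists lower in fasted knockout liver. Kupffer and macrophage markers lay lower (0 and 0 of 14, 0 higher and 2 lower adjusted over the list alone, median -0.38; camera adjusted p = 0.0215, adjusted p = 0.579 with an estimated correlation). The complement genes C1qc and C1qb were at -0.65 ± 0.17 (adjusted p = 0.12) and -0.70 ± 0.20 (0.13). The call was lost without control fasted replicates 2 (0.0672) or 3 (0.059), in a range of 0.000839 to 0.0672. Stellate markers lay lower (0 and 0 of 19, also over the list alone, median -0.19; 0.0395, adjusted p = 0.543 with an estimated correlation). That call was lost on the region nearest the TSS (0.151) and without control fasted replicates 1 (0.391) or 2 (0.0681), knockout fasted replicate 1 (0.0918) or control refed replicate 1 (0.0581), in a range of 0.00334 to 0.391.

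The remaining lists gave no camera call in fasted knockout liver. Lrp1, a lipoprotein receptor (0.27 ± 0.05, adjusted p = 0.026), Ahr, the aryl hydrocarbon receptor (-0.35 ± 0.07, 0.044), and the transporter Abcc4 (0.88 ± 0.18, 0.042) were the only other called members beside Afp and Acaa1b. Median-ratio rescaling ended each of the 3 calls, as it did that of Acaa1b (0.188, 0.0819, 0.0858 and 0.104). The highest adjusted p over all alternatives was 0.188 for Lrp1, 0.15 for Ahr, 0.174 for Abcc4 and 0.162 for Acaa1b. All 4 calls were also lost without control fasted replicates 1 or 3 and without knockout fasted replicates 1 or 3 (0.0521 to 0.174). Ahr, Abcc4 and Acaa1b were also lost without control refed replicate 3 or knockout refed replicate 1 (0.0531 to 0.0733). The same held for Ahr and Abcc4 without knockout fasted replicate 2, Ahr without control refed replicates 1 or 2 and Abcc4 without knockout refed replicate 2. camera adjusted p was 0.44 for LXR targets, 0.637 for lipoproteins (1 higher, 2 over the list alone), 0.192 for cholesterol synthesis, 0.761 for lipogenesis, 0.475 for bile acids and 0.639 for transcription factors. It was 0.877 for pericentral (1 lower, 1 over the list alone) and 0.596 for periportal genes (0 and 0, 2 lower over the list alone). It was 0.182 for the unfolded protein response, 0.567 for the clock, 0.0938 for interferon and 0.948 for fetal genes (1 higher and 1 lower, 1 and 2 over the list alone). It was 0.37 for proliferation, 0.225 for endothelial, 0.776 for lymphocyte and 0.225 for cholangiocyte markers (0 and 0, 2 higher and 1 lower over the list alone). Lists without a count here had 0 called members on either adjustment. Median and mean differed in sign for lipoproteins (-0.03 and 0.03) and transcription factors (-0.06 and 0.01), and camera pointed up for lipogenesis where both were negative.

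In refed liver, knockout against control asked what Gata4 does after a meal. Among the 4 called members of the fatty acid oxidation list was Cyp4a10. Its region (chromosome 4, 115184410 to 115195631, at the promoter) held 234 ± 50.5 in control and 581 ± 88.0 in knockout liver (log2 change 1.32 ± 0.18, adjusted p = 0.004). Cyp4a31 held 121 ± 12.7 and 292 ± 64.0 (2.38-fold, adjusted p = 0.003). No alternative ended either call. Cyp4a32 (0.58 ± 0.11, 0.015) and Cyp4a14 (1.20 ± 0.28, 0.041) rose too; quantile normalization ended the Cyp4a14 call (0.109) and median-ratio rescaling both (0.0715 and 0.0774). The highest adjusted p over their alternatives was 0.0746 and 0.136. Cyp4a32 was lost without knockout refed replicate 1 (0.0546), and Cyp4a14 without knockout refed replicates 1 (0.136) or 3 (0.115), control refed replicates 1 (0.087) or 2 (0.12) or knockout fasted replicates 2 (0.0514) or 3 (0.0551). These paralogs share sequence, and how reads that map to several of them were handled is not given in the sources used here. Fatty acid oxidation genes had 4 higher and 0 lower of 39 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0231, adjusted p = 0.762 with an estimated correlation). The list call was lost without knockout refed replicates 1 (0.163) or 3 (0.076), and its direction reversed without control refed replicate 2 (0.863), in a range of 8.11e-06 to 0.863.

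Some lists of metabolic genes and that of hepatocyte transcription factors lay on the lower side in refed knockout liver on 1 region per gene. Periportal and pericentral genes had no call (camera adjusted p = 0.637 and 0.471). Each gene was represented by its strongest region, and the knockout change fell with signal. Its median log2 was 0.30 in the lowest decile of mean value and -0.05 in the highest. camera called 7 lists of hepatocyte genes toward lower values, and each call was lost with an estimated correlation. The adjusted p was then 0.281 for LXR targets, 0.383 for transcription factors, 0.579 for lipoproteins, 0.281 for lipogenesis, 0.71 for bile acids, 0.768 for cholesterol synthesis and 0.662 for gluconeogenesis. Pltp, the phospholipid transfer protein, fell by 0.57 ± 0.10 on the log2 scale (1706 ± 44.8 to 1155 ± 119, adjusted p = 0.015) and Abcg8, a sterol exporter, by 0.59 ± 0.13 (0.031). These were the 2 fallen of 16 LXR targets (0 and 2 adjusted over the list alone; camera adjusted p = 0.00472). Hnf4a, a central hepatocyte transcription factor (-0.27 ± 0.05, 0.023), and Zfpm1, a cofactor of GATA factors (-0.36 ± 0.09, 0.046), fell among 21 such factors (0 higher and 2 lower, 0 and 4 over the list alone; 0.00533). Lipoprotein genes had 0 higher and 1 lower (0 and 2; 0.00472), lipogenic genes 0 and 0 on either adjustment (0.000982), and bile acid genes 0 and 0 (1 and 4; 0.0395). Cholesterol synthesis genes had 1 and 0 (1 and 0; 0.042) with the mevalonate kinase Mvk at 0.86 ± 0.20 (0.039), and gluconeogenic genes 0 and 0 (0 and 2; 0.0378). In the same order, each call was also lost with quantile normalization (0.0537, 0.515, 0.452, 0.406, 0.962, 0.727 and 0.861) and either lost or reversed with the mean over all regions of a gene (0.182, 0.592, 0.482, 0.592, 0.482, 0.0988 and 0.0114), with reversal for transcription factors and gluconeogenesis. On the region nearest the TSS those of transcription factors (0.18), bile acids (0.279), cholesterol synthesis (0.0587) and gluconeogenesis (0.286) were lost. Over their alternatives the adjusted p ranged from 0.00215 to 0.182, 0.00148 to 0.592, 8.15e-06 to 0.482, 4.2e-05 to 0.592, 0.000133 to 0.962, 0.0102 to 0.727 and 0.000674 to 0.861. Over all regions of the same genes the called ones were 1 higher and 3 lower of 85 for LXR targets, 3 and 2 of 211 for transcription factors, 9 and 2 of 164 for lipoproteins and 2 and 1 of 142 for lipogenesis. They were 0 and 0 of 144 for bile acids, 4 and 0 of 102 for cholesterol synthesis and 11 and 0 of 226 for gluconeogenesis, so of these lists only LXR targets had more called regions lower than higher. The median and mean of the gluconeogenic genes differed in sign (-0.13 and 0.03).

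Single libraries also ended calls of these lists and members. Without control refed replicate 1 the calls of lipoproteins (0.372), bile acids (0.937), cholesterol synthesis (0.138), gluconeogenesis (0.597) and transcription factors (0.064) were lost. Without control refed replicate 3 those of cholesterol synthesis (0.0504) and gluconeogenesis (0.0651) were lost. Without knockout refed replicate 1 that of bile acids (0.0723), without replicate 2 that of gluconeogenesis (0.0959), and without replicate 3 those of cholesterol synthesis (0.293), bile acids (0.14) and gluconeogenesis (0.0889) were lost. Quantile normalization ended the calls of Abcg8 (0.0528), Hnf4a (0.11), Zfpm1 (0.206) and Mvk (0.164), but not that of Pltp. Pltp was lost without knockout refed replicate 3 (0.0522), as were Abcg8 (0.107), Hnf4a (0.0532) and Mvk (0.145). The highest adjusted p over all alternatives was 0.0522 for Pltp, 0.107 for Abcg8, 0.141 for Hnf4a, 0.206 for Zfpm1 and 0.164 for Mvk. Abcg8 was further lost without control refed replicates 1 (0.0889) or 3 (0.0779) or knockout refed replicate 2 (0.096). Hnf4a was lost without control refed replicates 2 (0.0515) or 3 (0.0534) or knockout refed replicate 2 (0.0847). Mvk was lost without each of the 3 knockout fasted and 3 control refed libraries and without knockout refed replicate 1 (0.0518 to 0.111). Zfpm1 was lost without control fasted replicates 2 or 3, each knockout fasted library, control refed replicates 2 or 3, or knockout refed replicates 1 or 2 (0.0508 to 0.153).

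Among cell type markers in refed knockout liver, stellate markers lay lower with 0 called members of 19 on either adjustment (median -0.14; camera adjusted p = 0.00795, adjusted p = 0.344 with an estimated correlation). Hand2 was at -0.48 ± 0.16 (0.13) and Col1a2 at -0.66 ± 0.24 (0.16). Besides the estimated correlation, no alternative run for lists ended the list call. Sinusoidal endothelial markers lay lower too (0 of 25 on either adjustment; 0.0183, adjusted p = 0.579 with an estimated correlation). That call was lost with quantile normalization (0.0707), with the mean over all regions (0.335) and without knockout refed replicate 1 (0.101), in a range of 0.000926 to 0.335. Over all regions 1 was called higher and 0 lower of 75 for stellate and 3 higher and 0 lower of 286 for endothelial markers. Kupffer (0.849), lymphocyte (0.776) and cholangiocyte (0.639) markers had 0 called members on either adjustment and no list call. Afp was lower in refed knockout liver as well (252 ± 23.8 to 161 ± 37.7, -0.66 ± 0.15, 0.04), 1 of 8 fetal liver genes (0 higher and 1 lower, 2 and 2 over the list alone; 0.879). It was lost with only the refed groups (0.0898) and with edgeR (0.0526), and without each of the knockout fasted and control refed libraries and knockout refed replicates 1 and 2 (0.0523 to 0.129). Ctsc among periportal genes (0.66 ± 0.14, 0.027; 1 higher and 0 lower of 19, 1 and 1 over the list alone; 0.637) and Tef among clock genes (0.31 ± 0.07, 0.046; 1 and 0 of 22, 5 and 4 over the list alone; 0.471) rose. Median-ratio rescaling ended both calls (0.0826 and 0.224), with a highest adjusted p of 0.0999 and 0.227 over all alternatives. Each was also lost without control refed replicates 2 or 3 or knockout refed replicates 1 or 2 (0.0543 to 0.124). Tef was lost without control fasted replicate 2, knockout fasted replicate 1, control refed replicate 1 or knockout refed replicate 3 (0.0547 to 0.143). The other lists had camera adjusted p of 0.471 for pericentral, 0.309 for the unfolded protein response, 0.843 for the acute phase, 0.0938 for interferon (0 and 0, 2 higher over the list alone) and 0.471 for proliferation genes, with 0 called members where no count is given. Median and mean differed in sign for periportal, acute phase and lymphocyte genes.

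By size of change, the rule named rises near Klf2, a shear-responsive transcription factor (47.8 ± 18.3 to 263 ± 49.5; 2.50 ± 0.33, adjusted p = 0.004), Sox11 (2.38 ± 0.40), Mad1l1 (1.55 ± 2.68 to 29.3 ± 4.84, the former under the floor) and Mup20, a major urinary protein (7.24 ± 12.5 to 79.3 ± 47.3). Others lay near Fendrr (0 in all 3 controls, at least 5.54-fold higher), Nifk, Marveld2, Defb1 and Tfap2d. Falls lay near L1td1 (325 ± 93.6 to 52.9 ± 24.0; -2.66 ± 0.43), Fzd7, a Wnt receptor (342 ± 11.1 to 110 ± 45.8; -1.70 ± 0.21), and Fabp5, a fatty acid binding protein (541 ± 63.0 to 193 ± 21.1; -1.48 ± 0.26), each with a GATA4 peak. They also lay near Smek1 (-1.87 ± 0.32), Cox7a2l, Muc13 (-1.59 ± 0.30), Atxn7l3b (-1.47 ± 0.27) and Ermp1. A region near Tnks was at 0 in all 3 refed knockouts and at 300 ± 4.81 in controls, at least 89.9-fold lower. In fasted liver it was also at 0 in all 3 knockouts, and at 452 on average in controls, of which replicate 1 was at 0. Its refed call was lost with edgeR (0.0706) and without each of the 6 refed libraries (0.0559 to 0.0687). Mad1l1, Klf2, Sox11, L1td1, Smek1, Fzd7 and Fabp5 kept their call under every alternative run for them. Of the 20 regions that the rule picked by size, 12 did not. Fitting only the refed groups ended 9 calls, quantile normalization 7, and leaving out knockout refed replicates 1 or 2 ended 9 each. Leaving out control refed replicates 3, 2 and 1 ended 7, 5 and 4, knockout refed replicate 3 ended 4, and each fasted library 3 or fewer.

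In total 1100 regions rose and 189 fell in refed knockout liver, 2.02% of those tested, so that 85.3% of the called regions were higher. The split depended on scaling: 219 rose and 105 fell with quantile normalization (67.6%), 474 and 227 with median-ratio rescaling (67.6%) and 408 and 140 with cyclic loess (74.5%). They were 437 and 170 with edgeR's TMM (72.0%) against 1005 and 179 with edgeR on library totals (84.9%), and 1555 and 1168 with DESeq2's size factors (57.1%) against 2414 and 502 with DESeq2 on library totals (82.8%). The median log2 change over all regions was 0.10 as deposited, -0.02 after quantile normalization and 0.00 after cyclic loess. The total of 1289 became 2900 with array quality weights and 673 with only the refed groups. It was 738 without control refed replicate 2, 820 without replicate 3, 365 without knockout refed replicate 1, 462 without replicate 2 and 524 without replicate 3. Promoters were 1.36% of the risen regions against 7.03% of those not called (odds ratio 0.183, two-sided Fisher exact adjusted p = 4.1e-18) and 5.82% of the fallen (0.817, 0.668). In fasted knockout liver they were 1.01% of the risen (0.136, 0.000168) and 3.21% of the fallen regions (0.443, 0.0915). These shares were not matched on value and width and were not repeated after rescaling, so signal and width may contribute to them. At an adjusted p under 0.01 the odds ratio of the risen regions was 0.452 in refed (0.346) and 0 in fasted liver (1), and within 1000 bp of a TSS that of the fallen fasted regions was 0.568 (0.0411).

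Some regions changed with knockout in both feeding states. Called higher in both were 27 and lower in both 26, against 3.44 and 0.463 for independent lists, and 4 were called in opposite directions. Across all regions the changes correlated with Pearson r = 0.22 and Spearman rho = 0.25. Of those lower in both, the examples that follow were chosen after their values were seen. They lay near Afp, Muc13, Atxn7l3b, the chemokine gene Ccl2 (-1.41 fasted, -1.35 refed) and the steroid dehydrogenase Hsd3b5 (-1.18 and -1.10, at its promoter). Others lay near the transcriptional repressor Bcl6 (-0.71 and -0.89), the lipid droplet hydrolase Ldah (-1.36 and -1.05) and Srebf1 (-0.89 and -0.43, the bound region upstream, whose refed adjusted p was 0.0436). That refed call was lost with quantile normalization (0.0986), cyclic loess (0.0845), without each of the 6 refed libraries and without control fasted replicate 2 or knockout fasted replicates 2 or 3 (0.0503 to 0.141), with 0.141 the highest over all alternatives. Of those higher in both, Sox11, Nr1d2, Nrn1, Foxo1, a transcription factor restrained by insulin (1.21 fasted), and Adamts1 (3.98 in control and 147 in knockout fasted liver, and at 0 in all 3 refed controls against 174 in knockouts) were examples. Averaged over feeding states, 1906 regions rose and 567 fell with knockout (77.1% higher), with a share of 51.0% with median-ratio rescaling, 57.6% with quantile normalization, 64.4% with cyclic loess, 58.1% with edgeR and 51.7% with DESeq2, and of 77.5% with edgeR and 77.6% with DESeq2 on library totals. The total of 2473 was 1289 with quantile normalization, 1388 with cyclic loess, 5086 with DESeq2 and 4929 with DESeq2 on library totals. It was 1396 without control fasted replicate 1, 891, 1410, 1233, 1464 and 1447 without knockout fasted replicates 1 and 2 and knockout refed replicates 1, 2 and 3.

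Regions that lost acetylation in the knockout were often bound by GATA4 in the deposited table, which marks 5292 regions (8.31%) with a GATA4 ChIP peak within 500 bp; this comparison was added after the data were seen. Of the regions that fell in fasted knockout liver 56 of 156 were bound (35.9%) and of those that fell in refed knockout liver 72 of 189 (38.1%), against 8.25% and 8.31% of regions not called. The odds ratios were 6.23 (95% confidence interval 4.40 to 8.74, two-sided Fisher exact adjusted p = 2.1e-21) and 6.79 (4.98 to 9.20, adjusted p = 1.1e-28). Of the regions that rose, 5.53% and 3.27% were bound. Bound regions are wide and strong, and among uncalled regions matched on value and width 14.4% and 15.8% were bound, which left common odds ratios of 3.61 (2.54 to 5.13) and 3.48 (2.56 to 4.73). Neighbouring regions are not independent, and the libraries behind the GATA4 peaks are not part of this series.

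**Figure D4:**
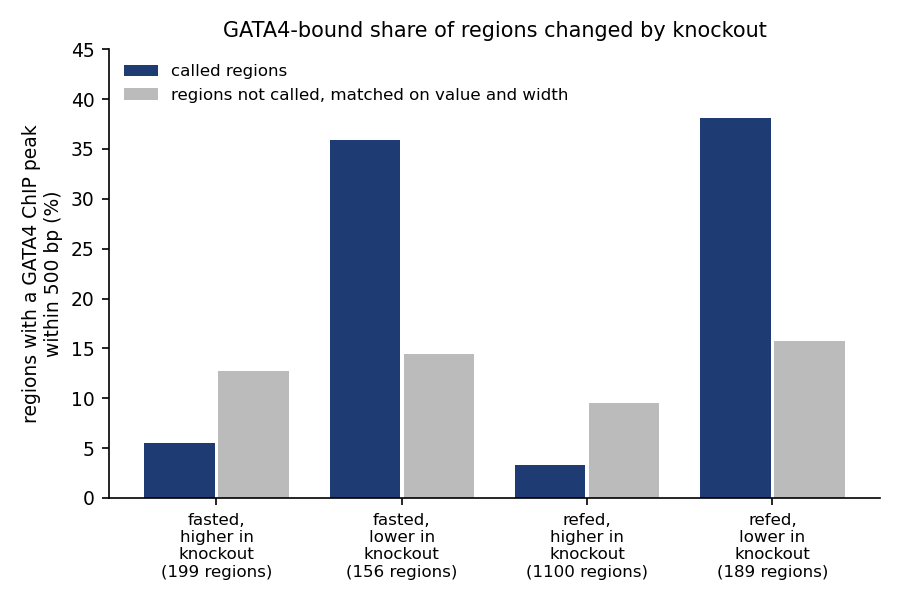
Percent of regions with a GATA4 peak within 500 bp among regions called higher or lower in knockout liver and among uncalled regions matched on value and width, in fasted and refed liver; bars start at 0. Bound shares are 35.9% and 38.1% of the fallen and 5.53% and 3.27% of the risen regions.

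The interaction of knockout and feeding passed the threshold in 15 regions, 10 toward higher and 5 toward lower values in refed liver. Of 100 regroupings of genotype within feeding state 7, the real one included, gave at least as many, so chance is not excluded for this count. None of the Cyp4a regions was among them, so their knockout change is not shown to differ between feeding states. Examples, chosen after their values were seen, were a region near Trim14 (393 in control and 126 in knockout fasted liver, 884 and 859 in refed liver; interaction log2 1.60 ± 0.19, adjusted p = 0.0105) and another near Ccdc172 (1189 and 746 fasted, 390 and 582 refed; 1.24 ± 0.17, 0.0259). The count was 28 with a pseudocount of 5, 71 with array quality weights, 64 with edgeR on library totals, 509 with DESeq2 and 597 with DESeq2 on library totals. Without 1 library it was 42 (control fasted replicate 1), 148 (control fasted 2), 40 (knockout fasted 2), 58 (control refed 1), 26 (control refed 2) or 9 (knockout refed 2).

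The other fixed genes of interest, each at its region with the highest mean, did not pass the threshold for knockout in either feeding state. Gata6 was at 0.38 ± 0.17 fasted (0.346) and 0.27 ± 0.17 refed (0.421). The cholesterol exporter Abca1 was at -0.05 ± 0.07 (0.832) and -0.21 ± 0.07 (0.143), and Srebf1 at -0.04 ± 0.10 (0.907) and -0.23 ± 0.10 (0.263). Fasn was at -0.09 ± 0.05 (0.484) and -0.08 ± 0.05 (0.486), Pck1 at -0.32 ± 0.19 (0.507) and 0.23 ± 0.19 (0.573) and Cyp7a1 at -0.09 ± 0.18 (0.887) and 0.22 ± 0.18 (0.568). With refeeding, Abca1 was at 0.12 ± 0.07 in control (0.253) and -0.05 ± 0.07 in knockout liver (0.708), and Gata6 at -0.05 ± 0.17 (0.847) and -0.16 ± 0.17 (0.54). Cyp7a1 fell in both (-1.10 ± 0.18 and -0.79 ± 0.18). Of the other regions of these genes, looked at after the data were seen, those called for knockout were the region upstream of Srebf1, 1 of 10 near Abca1 and 2 of 6 near Pck1. The Abca1 region (chromosome 4, 53198083 to 53200828) fell in fasted knockout liver (239 to 127; -0.90 ± 0.16, adjusted p = 0.0225). It was lost with only the fasted groups (0.0872) and without control fasted replicates 1 (0.0749) or 3 (0.0747) or knockout fasted replicate 1 (0.113, the highest over all alternatives). In refed liver a Pck1 region (chromosome 2, 173008886 to 173010617) rose from 23.2 to 74.1 (1.62 ± 0.22, adjusted p = 0.00395), which no alternative ended. The other Pck1 region (chromosome 2, 172993101 to 173000583) rose from 413 to 765 (0.88 ± 0.19, adjusted p = 0.0334). It was lost with median-ratio rescaling (0.0804), quantile normalization (0.073), cyclic loess (0.0583) and edgeR (0.0762), and without control refed replicates 2 (0.0993) or 3 (0.0605) or knockout refed replicates 1 (0.111, the highest over all alternatives) or 2 (0.105).

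The authors' own deposited comparisons were longer except for genotype. Their fasted table listed 2021 regions, 1207 higher and 814 lower in knockout liver, and held 298 of the 355 regions called here (83.9%). Their refed table listed 4200, 2974 higher and 1226 lower, and held 1107 of 1289 (85.9%). Their genotype table listed 301 regions, 70 higher and 231 lower in knockout liver once its sign was set from the values, and its log2 ratios followed the fasted comparison (r = 0.966 across regions) more closely than the average (0.876). It held 214 of the 2473 regions called here for the average effect (8.65%), and 23.3% of its regions were higher in knockout liver against 77.1% here. Their interaction table listed 972 regions and held all 15 called here, and their adjusted p for control refeeding covered 20390 regions and 16516 of the 19083 called here (86.5%).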

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

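Tests of the zeros against a processing step and against feeding state, of the excess of higher regions against scaling and background, and of the bound share against width and strength were chosen after the result was seen. In 15 regions the interaction of knockout and feeding passed the threshold. The interaction log2 changes, refed minus fasted, were 7.89 near Pou4f1, -2.99 near Gm13490, 1.60 near Trim14, -3.73 near Lrp2bp, 4.59 near F2r, 4.10 near Redrum, 1.60 near Gm3143 and -4.69 near Rprm. They were 1.24 near Ccdc172, 1.98 near Mir1904, -1.73 near Mcm5, -0.87 near Ppil1, 9.66 near 1700029F12Rik, 2.88 near 2310057J18Rik and 3.61 near Nipbl. The fitted values near Pou4f1, Lrp2bp, Redrum and Rprm, each with a group at 0, and near 1700029F12Rik, with a group mean of 0.67, depend on the pseudocount and do not measure a fold. Of 100 regroupings of genotype within feeding state, 7, the real one included, gave at least 15 regions, so chance is not excluded for this count. The highest other regrouping gave 2473, which follows from the structure of the design: swapping the genotype labels in 1 feeding state turns the interaction into the average effect. For the average effect 1 of 100 regroupings, the real one, gave as many as 2473 regions and the highest other 30, which argues against chance for this count. Regrouping cannot tell knockout apart from a cage or litter shared within a group. For the 4 simple comparisons 10 splits are too few for a share under 0.05: the real split, 1 in each, gave 355, 1289, 19083 and 15718 regions and the highest other 6, 6, 1 and 3.

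Some regions with many reads in most libraries were at exactly 0 in others, among them those near Pdcl3, Reck, Adam24 and Fendrr. In regions with a mean of 50 or more there were 551 values at 0, in 283 of 40633 regions, against at most 196 in 20 sets of simulated reads, which argues against counting noise. In every library regions at 0 outnumbered those at 1, 2 or 3 reads each, by a lowest ratio of 1.87, as a step that sets low values to 0 would give; whether the authors took such a step is not given in the sources used here. Of 41 regions at 0 in exactly 6 libraries, 31 (75.6%) were at 0 in all libraries of 1 feeding state, 24 fasted and 7 refed, against 0.216% by chance, and 0 of the 41 followed genotype. Without the limit to 6 libraries, 26 regions were at 0 in all fasted and 7 in all refed libraries but not in all of the other state. For genotype 2 were at 0 in all knockout libraries, among them the region near Tnks, and 2 in all control libraries. Zeros that follow feeding state may thus combine low acetylation with a step that removed the remaining reads. Folds of these regions are uncertain, as are their lower bounds.

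The excess of higher regions in refed knockout liver could have technical sources. With reads thinned to the smallest library 1074 regions were still called higher against 1100, which argues against depth. The knockout change fell with signal, from a median log2 of 0.30 in the lowest decile of mean value to -0.05 in the highest. Refed knockout libraries had median values of 91.5 to 94.5, and refed controls 77.7 to 83.5. Their top 100 regions held 4.73% to 4.81% and 5.05% to 5.32% of reads, as a lower ratio of signal to background would give. After cyclic loess, which removes a trend with signal, 74.5% of the called regions were higher. The number called higher fell from 1100 to 408, so such a trend accounts for part of the excess but not for the whole. After quantile normalization 67.6% were higher, in a range of 57.1% to 74.5% over 5 rescalings. The lowest share came from DESeq2, another test, which called 2723 regions. On library totals it gave 82.8%, so its lower share follows from its size factors. Median-ratio rescaling in limma left 67.6%. For each test, rescaling lowered the number and share of higher regions. Scaling every library to the same total thus stays open, as does a true gain, since each rescaling assumes no global change.

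Regions that fell in knockout liver were often GATA4-bound, and a candidate explanation is loss of GATA4 from these regions. Against uncalled regions of like value and width the bound share was at least 2.41 times as high in both feeding states, which argues against the power of wide and strong regions as the whole cause. After cyclic loess the lower of both ratios was 2.78, which argues against a lower ratio of signal to background. Among the 200 falling regions with the lowest p in refed liver 39% were bound with the real grouping, 1 of 10 splits, and at most 20.5% with another; 10 splits are too few for a share under 0.05. A cage or litter shared within a group stays open, and the GATA4 peaks come from other libraries.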

How the results depend on the processing

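The alternatives with regions at 0 left out, thinned reads, or edgeR or DESeq2 on library totals, and the bound shares after rescaling, were chosen after seeing the data. No paired analysis was possible because the numbers of the mice are shared within groups and not between them. The GATA motif comparison, with its variants WGATAR and whole region, was not run. With 3 mice per group and 200 changed regions, 38% to 44% of simulated 2-fold changes were recovered over the 4 simple comparisons, so that many changes of this size may be missed where few regions change. Where many were called, smaller changes passed: in control refeeding 3142 of 8378 rises were over 2-fold. Refeeding counts stayed within 1.5 times under every alternative run, with 15277 to 18822 in control and 11659 to 16440 in knockout liver as single libraries were left out. Of 6480 alternatives for 251 called named regions 6083 kept the call, 397 lost it and 0 reversed; of 495 for 33 called lists 425 kept it, 66 lost it and 4 reversed. For lists not called, 677 of 765 stayed so, 19 became called and 69 moved in direction; for regions not called the counts were 4351, 123 and 14 of 4488. No camera call held with an estimated correlation. Where not stated, the cause was not tested.

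In fasted knockout liver the count of 355 became 59 with only the fasted groups in the fit, a smaller fit, 1178 with DESeq2 and 1431 with DESeq2 on library totals. It ranged from 105 to 918 as 1 library was left out: 179, 918 and 163 without control fasted replicates 1, 2 and 3, 105 and 187 without knockout fasted replicates 1 and 3, and 233 without control refed replicate 3. In refed knockout liver 1289 became 701 with median-ratio rescaling, 324 with quantile normalization, 548 with cyclic loess, 2900 with array weights, 673 with only the refed groups, 607 with edgeR, 2723 with DESeq2 and 2916 with DESeq2 on library totals. It ranged from 365 to 1423: 738 and 820 without control refed replicates 2 and 3, and 365, 462 and 524 without knockout refed replicates 1, 2 and 3. The interaction count of 15 became 28 with a pseudocount of 5, 71 with array weights, 64 with edgeR on library totals, 509 with DESeq2 and 597 with DESeq2 on library totals. It ranged from 9 to 148: 42 and 148 without control fasted replicates 1 and 2, 40 without knockout fasted replicate 2, 58 and 26 without control refed replicates 1 and 2, and 9 without knockout refed replicate 2. The averaged knockout count of 2473 became 1289 with quantile normalization, 1388 with cyclic loess, 5086 with DESeq2 and 4929 with DESeq2 on library totals. It ranged from 891 to 2545: 1396 without control fasted replicate 1, 891 and 1410 without knockout fasted replicates 1 and 2, and 1233, 1464 and 1447 without knockout refed replicates 1, 2 and 3.

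Of 84 list tests 33 were called, 21 with quantile normalization and 26 to 35 as 1 library was left out. With the mean over all regions of a gene, gluconeogenesis reversed in fasted (adjusted p = 0.93) and refed knockout liver (0.0114) and hepatocyte transcription factors in refed knockout liver (0.592); fatty acid oxidation reversed there without control refed replicate 2 (0.863), in a range of 8.11e-06 to 0.863 over the libraries left out. The correlation of refeeding changes of 0.77 became 0.815 without the regions of lowest mean value and 0.740 to 0.768 without 1 library, and that of knockout changes 0.181 to 0.237. The Gata4 region stayed uncalled at 0.15 to 0.22 in fasted and 0.10 to 0.19 in refed liver. At an adjusted p under 0.01 the promoter odds ratio of risen regions went from 0.136 to 0 in fasted (adjusted p = 1) and from 0.183 to 0.452 in refed knockout liver (0.346), with fewer regions called. Within 1000 bp of a TSS that of fallen regions in fasted knockout liver went from 0.443 to 0.568 (0.0411).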

Other observations

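The test of the hypothesis below was written before its result was seen, and the genes of the first paragraph were chosen after their values were seen. Several genes had more than 1 called region. In refed knockout liver 9 of 25 regions annotated to Trim24, a nuclear receptor cofactor, rose (4 with quantile normalization). So did 6 of 25 near the hepatic lipase gene Lipc (3; log2 1.02 to 1.68), 5 of 20 near the estrogen receptor gene Esr1 (2) and 4 of 10 near Cyp4a10 (2). Of 6 regions near Fabp5, 2 fell (2 with quantile normalization). In fasted knockout liver 6 of 23 regions near Mbnl2, a splicing regulator, rose (6; 0.71 to 1.72), and all 3 near Tcf24 (3; 1.58 to 3.11).

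fry tests a list for movement in 1 direction without comparing it with other genes. With refeeding, LXR targets moved up in control (adjusted p = 6.2e-05, median log2 0.14) and knockout liver (0.000607, 0.01). Lipogenic genes did too (9.26e-07 and 3e-06), and lists share genes. No alternative was run for fry. In refed knockout liver its adjusted p toward lower values was 0.0041 for LXR targets, 0.00985 for lipogenic genes, 0.019 for hepatocyte transcription factors and 0.0209 for stellate markers. Of the lipogenic genes 0 of 29 were called there on either adjustment, and over all their regions 2 were higher and 1 lower of 142. The camera calls of LXR targets, lipogenic genes and transcription factors there were lost with quantile normalization (0.0537, 0.406 and 0.515). In fasted knockout liver stellate (0.022) and Kupffer markers (0.0417), with 0 called members each, moved toward lower values. Fatty acid oxidation genes, called by camera in both knockout comparisons, had fry adjusted p of 0.303 and 0.369. With refeeding, cholangiocyte markers moved toward higher values in control (0.000649) and knockout liver (0.00139), and proliferation genes in both (0.0145 and 0.0111). So did unfolded protein response genes in both (0.0111 and 0.00621), cholesterol synthesis genes in both (0.019 and 0.0165), and interferon genes (0.0111) and Kupffer markers (0.019) in knockout liver. Periportal (0.000649 and 0.0041), fatty acid oxidation (0.0041 and 0.00329) and acute phase genes (0.0209 and 0.00329) moved toward lower values in both, and bile acid genes in knockout liver (0.0209). No other list reached an adjusted p under 0.05 with fry.

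A hypothesis was that refed knockout liver may hold more of the fasting signal, as the higher values at Cyp4a10 and Cyp4a31 in refed knockout liver would have it. The knockout change in refed liver was correlated across regions with the refeeding change in control liver, with no library used on both sides, leaving each control refed library in turn to 1 side. Pearson r was -0.278 to -0.191, so that a feeding response reduced in knockout liver has the values it needs; regions are not independent replicates. After cyclic loess r was -0.260 to -0.172, and after quantile normalization -0.203 to -0.130. In fasted liver, where the control fasted libraries were shared out in the same way, r was -0.061 to 0.106. The interaction, which tests such a difference directly, passed in 15 regions, and 7 of 100 regroupings, the real one included, gave at least as many. With refeeding 21 of 39 fatty acid oxidation genes were called lower in knockout and 17 in control liver. For their regions the counts were 71 and 76, so counts point both ways. A property shared by the 3 control refed libraries stays open although -0.172 met the bound set against it. That bound was wrong, because loess removes only a trend with signal, and any other shared property is confounded with group.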
